A study of Homo sapiens with 8 samples.

How the data were processed

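Human heart RNA was measured on 8 two-colour Agilent oligonucleotide arrays, each carrying fetal heart RNA in one dye and adult heart RNA in the other. The description in the labels calls both commercial polyA RNA samples, amplified and labelled by the standard Agilent protocols, while the molecule field of the same labels reads total RNA; which holds was not settled here. On 4 arrays the fetal RNA carried Cy5 and the adult RNA Cy3; on the other 4 the dyes were exchanged. Arrays are numbered 1 to 4 within each orientation, as in the labels. The labels name no separate donors and do not state whether the arrays shared the same RNA extracts. The p-values therefore measure only the spread between these arrays, which may be technical, and they compare these RNA preparations. For that reason the number of genes past the size threshold without any test is given beside the tested count.

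Per the labels, the arrays were processed with Feature Extraction version 7.1, and only good features were reported, with saturated and outlier features removed. The deposited values are log10 ratios of Cy5 over Cy3, which was inferred as follows. Feature Extraction writes its ratio as log10 of Cy5 over Cy3, the values end at 2 and -2 (a limit of 100-fold), and the 2 orientations had opposite signs across probes. The value table itself states neither scale nor direction, and how the dyes were normalized is not given in the sources used here. The median deposited log10 value was 0 on each of the 8 arrays, so the values lie centred between the dyes, with the step that centred them unknown. Most values carry 2 decimals, so ratios come in steps and several arrays can hold the same value. Removal of saturated features can leave out the brightest probes on some arrays, which affects abundant transcripts of heart muscle and blood.

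The value table held 43928 features. The probe annotation given with it named 29127 of them, of which 29030 had 1 gene symbol and 97 had several; the remaining 14801 features were unnamed here. Gene IDs of 28989 probes (99.53%) matched the RefSeq gene table of assembly GRCh38.p14, which was used only to update symbols. Probes of Y-linked genes, XIST and TSIX were left out everywhere (69 probes), which left 29058. Control features are not marked in the value table, so only annotated probes entered the analysis. Of these, 29040 were measured on at least 3 arrays of each orientation and were tested, and 18 were not. Probes with several symbols entered the probe counts but named no gene. For each gene, the ratios of its probes were averaged within each array, giving 17953 genes, 7390 of them with more than 1 probe.

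Each deposited log10 ratio was converted to log2 and turned to fetal over adult, so that a positive value is higher in the fetal RNA. The ratios were fitted with limma (version 3.58.1, R version 4.3.3; lmFit and eBayes, two-sided) with an orientation term coded 1 and -1, so the intercept is the dye-balanced log2 ratio and the orientation coefficient measures dye bias. A probe or gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1 (2-fold). Dye bias was called at an adjusted p under 0.05 and an absolute coefficient of at least 0.5. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 19 lists. Where an array lacked a value, the fitted value of that gene stood in for camera alone. The lists and tests, the comparison design and the rule for named genes were fixed before the data were examined, and the design was followed as written.

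The 19 lists were cell cycle, erythroid, developmental growth and imprinted genes, sarcomere, fatty acid oxidation, oxidative phosphorylation, glycolysis and glucose uptake, calcium handling and ion channels, cardiac transcription factors and signals, extracellular matrix, immune cell markers, adipocyte markers, immediate early and stress genes, endothelial markers, smooth muscle and pericyte markers, skeletal muscle markers, neural and Schwann markers, hepatic and plasma protein genes, and ribosomal proteins. Named genes were the 10 genes with the largest ratio in each direction among those past the threshold, with one sign on every array that measured them, at least 6 arrays and a symbol that is not a clone or open reading frame name; up to 4 members past the threshold with the largest ratio in each list; and a fixed panel of cardiac, blood, growth and control genes whatever their result. Genes named beyond this rule were chosen after their values were seen, and this applies to list members that went against their list and to the lists of the closing section.

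Alternatives fixed in advance were median centring, scale normalization, measurement on all 8 arrays or on at least 2 per orientation, leaving out each array, the array number as a replicate block, no orientation term, each orientation alone, robust eBayes, a threshold of 1.5-fold or none, reading the values as log2, averaging without a test, 1 probe per gene, camera with an estimated correlation, and comparison with 10000 random lists of the same size. Alternatives chosen after seeing the data were use of all features, exact zeros set to missing, and removal of the members of 4 of the 12 lists written after the ratios were seen (kidney, epithelial, neutrophil granule, and NF-kappa-B and cytokine response genes). The fit was tested on simulated ratios for the 29040 probes with the real dye coefficients, spread and blanks. It recovered 98 of 100 probes changed by 1.5 on the log2 scale and 100 of 100 changed by 2.5, and called 0 of 28840 unchanged probes with limma, of which 5.11% had an unadjusted p under 0.05. The simulated noise was independent and as small as that between these arrays, so changes of this size were easily found. Variation between RNA preparations was not simulated, so the rate of false calls in the real data is not shown. Precision is limited by the number of arrays, and brightness over background was not used here.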

Results

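Fetal and adult human heart RNA were compared directly on 8 two-colour arrays, 4 with the fetal RNA in Cy5 and 4 with the adult RNA in Cy5. The labels title the series as a screen on hearts and give no further purpose; the exchanged dyes allow the tissue difference and the dye bias of each probe to be measured separately. Between 97.64% and 99.98% of the 29058 annotated probes had a value on each array. Across probes, arrays of one orientation correlated with a mean Pearson r of 0.856 (12 pairs, range 0.819 to 0.883). Arrays of opposite orientation, once turned to fetal over adult, correlated with a mean r of 0.738 (16 pairs); as deposited this mean was -0.738. These correlations are across probes within the same experiment, and probes are not independent replicates. The median SD of a probe between arrays was 0.113 on the log2 scale with fetal RNA in Cy5, 0.0997 with adult RNA in Cy5, and 0.199 over all 8 turned arrays. Values below are log2 ratios of fetal over adult, given as mean ± SD of the arrays, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

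Chemokine, cytokine, proliferation, erythroid and matrix genes were higher in the fetal RNA, while genes of mitochondrial energy metabolism, the sarcomere and fat cells were higher in the adult RNA. At least 2-fold differences with an adjusted p under 0.05 were found for 1872 of 17953 genes (10.4%), of which 1031 were higher in fetal and 841 higher in adult RNA. Without a test, 1872 genes had a mean ratio of at least 2-fold, so the size threshold alone set this count. Of the tested calls, 1835 had one sign on every array that measured them, and 0 had opposite mean signs in the 2 orientations. At least 4-fold differences numbered 190 towards fetal and 113 towards adult, and at least 8-fold differences 49 and 16. At the level of probes, 3491 passed, 2068 higher in fetal and 1423 higher in adult RNA, and 3493 passed by size alone (2069 and 1424). The adjusted p alone was met by 13454 genes (74.9%), since the spread between arrays was small (median SE 0.0369). If the deposited values were read as log2 instead of log10, 46 genes would pass, 37 higher in fetal and 9 higher in adult RNA.

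**Figure D1:**
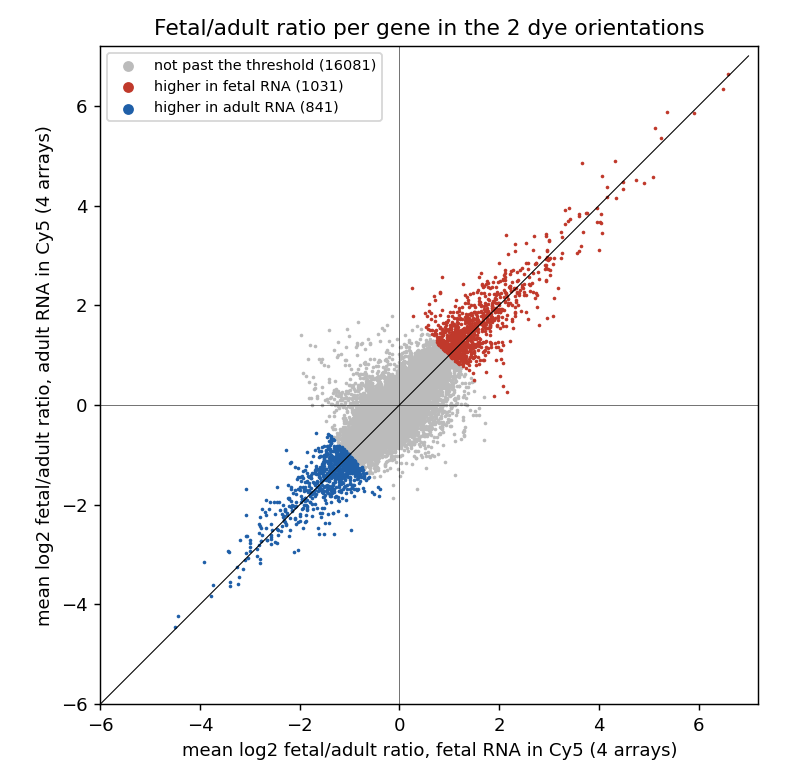
Mean log2 fetal/adult ratio of each gene on the 4 arrays with fetal RNA in Cy5 (horizontal axis) and the 4 with adult RNA in Cy5 (vertical axis), with the line of equality. Red points are the 1031 genes higher in fetal RNA and blue points the 841 higher in adult RNA; none of the called genes has opposite mean signs in the 2 orientations.

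The largest ratios towards fetal RNA, those of CXCL1, CXCL8, PTX3 and SELE, belonged to inflammatory mediators. The neutrophil-attracting chemokines CXCL1 (6.62 ± 0.05, SD, n = 8) and CXCL8 (6.41 ± 0.20) were at least 98-fold and 85.1-fold higher; CXCL1 sat at the 100-fold limit of the software on 5 of 8 arrays and CXCL8 on 2, so these ratios are lower bounds and their SDs are too small. PTX3, a secreted pattern recognition protein, was 58.7-fold higher (5.88 ± 0.09) and SELE, the endothelial adhesion molecule E-selectin, 49.4-fold (5.63 ± 0.29). The cytokine IL6 reached 25.6-fold (4.68 ± 0.28) and the IL-33 receptor IL1RL1 24.6-fold (4.62 ± 0.24). The epithelial adhesion molecule EPCAM was 40.4-fold higher (5.34 ± 0.34), the neutrophil defensin DEFA3 39.2-fold (5.29 ± 0.10), the secreted phosphoprotein SPP1 28.3-fold (4.82 ± 0.28, mean of 10 probes) and the potassium channel KCNJ16 24.3-fold (4.61 ± 0.33). All 10 genes were higher in fetal RNA on 8 of 8 arrays, and apart from CXCL1 and CXCL8, whose limited values shrink the spread, adjusted p-values ran from 2.12e-11 for DEFA3 to 1.24e-09 for EPCAM.

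In the opposite direction, CFD, the adipocyte-derived complement factor D, was 22.1-fold higher in adult RNA (-4.47 ± 0.07, n = 8), and the terminal complement component C6 20.2-fold (-4.33 ± 0.13). PERM1, a muscle regulator induced by PGC-1, stood at -3.80 ± 0.06, with its 2 probes at -4.38 and -3.22. The chloride channel family member CLIC6 (-3.67 ± 0.14), FAM81B (-3.53 ± 0.56), the scaffold protein HOMER2 (-3.52 ± 0.17) and the dynein subunit DYNC1I1 (-3.48 ± 0.18) followed. The lipid droplet protein PLIN4 (-3.42 ± 0.26), TMEM178B (-3.34 ± 0.28) and the matrix protein VIT (-3.25 ± 0.12) completed the 10. Each was lower in fetal RNA on 8 of 8 arrays, with adjusted p-values from 2.12e-11 for C6 to 8.62e-08 for FAM81B.

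**Figure D2:**
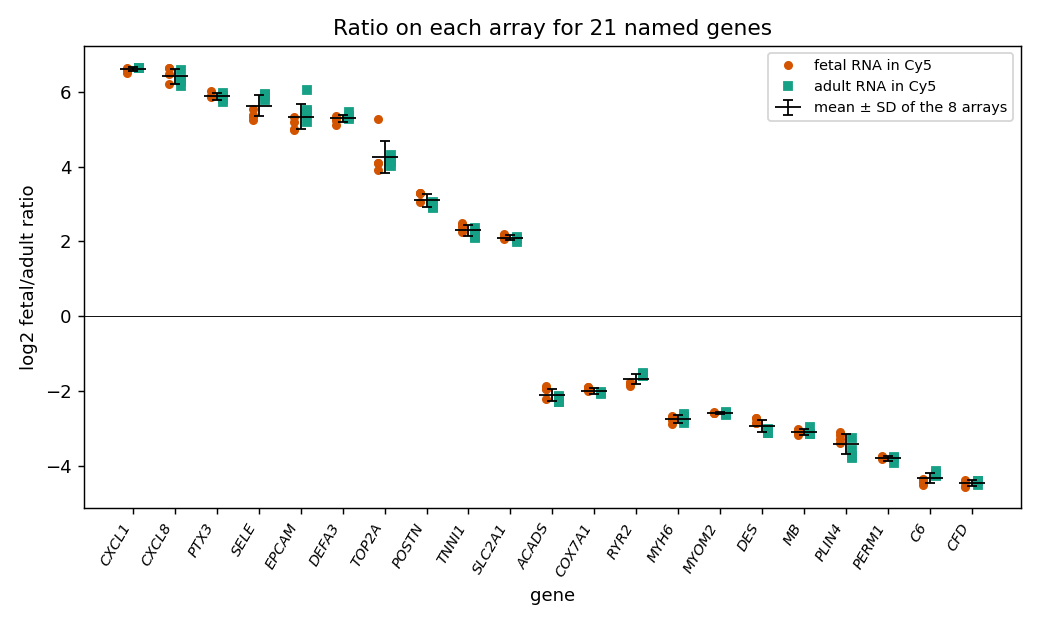
Log2 fetal/adult ratio (vertical axis) of 21 named genes (horizontal axis) on each array, circles with fetal RNA in Cy5 and squares with adult RNA in Cy5; dashes and bars give the mean ± SD of the arrays (8, or 7 for COX7A1). Each gene keeps one sign on every array, from CXCL1 at 6.62 (held down by the limit of the software) to CFD at -4.47; TOP2A has 1 array at 5.28, above its mean of 4.25.

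Among the 19 gene lists, 11 passed camera at an adjusted p under 0.05, and each of these except immune cell markers also passed with an estimated correlation. That correlation was estimated from the spread between these arrays, which may be technical, so it need not reflect how genes vary together between hearts. Counts of members past the threshold, adjusted over the list alone, equalled those over all genes in every list.

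Proliferation genes were higher in the fetal RNA. In the cell cycle list 22 of 48 tested members rose and 0 fell, with a median ratio of 0.91 (camera adjusted p = 5.52e-12). TOP2A, the DNA topoisomerase of dividing cells, was 19-fold higher (4.25 ± 0.43, n = 8, on 8 of 8 arrays), TYMS, which makes thymidylate, 15.2-fold (3.93 ± 0.16), the kinetochore protein CENPF 7.27-fold (2.86 ± 0.43) and the checkpoint kinase BUB1 6.82-fold (2.77 ± 0.54). MKI67, the proliferation antigen Ki-67, had a ratio of 0.67 ± 0.63 with an adjusted p of 0.013 in limma, under the size threshold, and was positive on 7 of 8 arrays.

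Genes of red cell precursors were also higher. In the erythroid list 14 of 20 members rose and 1 fell, with a median of 1.65 (camera adjusted p = 4.59e-06). HBM, a globin of the alpha cluster, was 11.9-fold higher (3.58 ± 0.17), the adult-type alpha globin HBA2 11.8-fold (3.56 ± 0.48), and ALAS2, the first enzyme of haem synthesis in red cells, 4.59-fold (2.20 ± 0.19). The embryonic globin HBE1 averaged 2.77 ± 1.02, but its 2 probes stood at 5.07 and -0.24, and the second was blank on 1 array; with 1 probe per gene HBE1 stood at 5.07. ANK1, an ankyrin of the red cell membrane that muscle also makes, was lower in fetal RNA (-1.75). A second HBA2 probe, measured only on the 4 arrays with adult RNA in Cy5, had a mean of 0.91, against 3.11 for the tested probe on those arrays.

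Growth and matrix genes followed the same direction. Of the developmental growth and imprinted genes, 12 of 25 rose and 0 fell (median 0.81, camera adjusted p = 1.53e-06), among them the RNA-binding protein IGF2BP3 (2.11 ± 0.22, 4.33-fold), the transcription factor SOX4 (1.93 ± 0.09) and the imprinted genes MEST (1.87 ± 0.14) and PEG10 (1.77 ± 0.23). In the extracellular matrix list 19 of 49 rose and 1 fell (median 0.78, camera adjusted p = 8.73e-09). POSTN, a matrix protein of valves and remodelling tissue, was 8.54-fold higher (3.09 ± 0.17), followed by the collagens COL3A1 (2.52 ± 0.15), COL11A1 (2.31 ± 0.44) and COL5A1 (1.99 ± 0.30). For COL3A1, 4 of 5 probes lay between 2.64 and 3.69 and 1 lay at -0.04. That last probe read exactly 0 on every array except array 1 of each orientation (0.83 with fetal and -1.16 with adult RNA in Cy5). It lowers the average given for the gene. MGP, an inhibitor of calcification, was the member that fell (-1.33).

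Stress and ribosomal genes differed as groups. In the immediate early and stress list 15 of 36 rose and 0 fell (median 0.48, camera adjusted p = 1.67e-07). Besides IL6, these were led by the monocyte chemokine CCL2 (3.71 ± 0.16, 13.1-fold) and the heat shock proteins HSPA6 (3.15 ± 0.13) and HSPH1 (2.51 ± 0.18). Of 55 ribosomal proteins 54 had a positive ratio, but only 4 rose by the size threshold (median 0.48, camera adjusted p = 1.18e-14): RPS19 (1.18 ± 0.07), RPS6 (1.09 ± 0.19), RPL5 (1.03 ± 0.07) and RPS3A (1.003). RPS3A was at the threshold and left it without array 4 with fetal RNA in Cy5 (0.9998) and without arrays 1 (0.9984) or 4 (0.9957) with adult RNA in Cy5, with fetal RNA in Cy5 alone (0.991) and with probes measured on all 8 arrays (0.9602). RPL5 and RPS6 left it with fetal RNA in Cy5 alone (0.99 and 0.92) and with 1 probe per gene (0.68 and 0.74).

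Genes of mitochondrial energy metabolism were lower in the fetal RNA. In the oxidative phosphorylation list 33 of 57 fell and 0 rose (median -1.05, camera adjusted p = 5.65e-17). COX7A1, the muscle form of a cytochrome c oxidase subunit, was 3.98-fold lower (-1.99 ± 0.08, n = 7), the complex III core protein UQCRC1 3.35-fold (-1.74 ± 0.46), and the complex I subunits NDUFB9 and NDUFB10 stood at -1.61 ± 0.07 and -1.55 ± 0.11. In the fatty acid oxidation list 23 of 33 fell and 0 rose (median -1.18, camera adjusted p = 2.29e-09). The acyl-CoA dehydrogenases ACADS (-2.11 ± 0.17, 4.32-fold, n = 8) and ACADVL (-2.03 ± 0.08, n = 7) fell most, followed by the thioesterase ACOT2 (-1.87 ± 0.09) and the electron transfer flavoprotein ETFB (-1.81 ± 0.05). CPT1B, the muscle enzyme that passes fatty acids to mitochondria, had a ratio of -0.93 ± 0.23 and PDK4, an inhibitor of pyruvate oxidation, -0.21 ± 0.12, both under the size threshold. CPT1B passed it on the arrays with adult RNA in Cy5 alone (-1.14).

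Contractile genes were lower as a group in the fetal RNA, with a fetal isoform higher. In the sarcomere list 12 of 27 fell and 1 rose (median -0.87, camera adjusted p = 0.000326; 0.045 as adjusted p with an estimated correlation). The alpha myosin heavy chain MYH6 was 6.72-fold lower (-2.75 ± 0.10, n = 8), the M-band protein MYOM2 6.04-fold (-2.60 ± 0.03) and the ventricular light chain MYL2 4.02-fold (-2.01 ± 0.08). TNNI1, the slow skeletal troponin I of the fetal heart, was 4.91-fold higher (2.30 ± 0.14), whereas the adult cardiac form TNNI3 was 2.71-fold lower (-1.44 ± 0.03, n = 7). The atrial and fetal light chain MYL4 had a ratio of 0.83 ± 0.11, under the size threshold, and the atrial light chain MYL7 0.03 ± 0.11 (adjusted p = 0.162 in limma).

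Fat cell markers had the lowest median of all 19 lists. In the adipocyte list 11 of 15 fell and 0 rose (median -2.05, camera adjusted p = 6.19e-06), led by CFD and PLIN4, the hormone leptin, LEP (-2.99 ± 0.62), and the lipid droplet protein PLIN1 (-2.87 ± 0.12).

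Immune cell markers were split. In this list 7 of 35 fell, 2 rose and 26 did not pass (median -0.30, camera adjusted p = 0.0382), and the adjusted p was 0.076 with an estimated correlation. The members that fell included the MHC class II genes HLA-DMA (-1.55 ± 0.20), HLA-DPB1 (-1.54 ± 0.12) and the invariant chain CD74 (-1.36 ± 0.20), while S100A8, a calcium-binding protein of neutrophils and monocytes, was 4.86-fold higher (2.28 ± 0.10). The list's call was also lost without array 1 with fetal RNA in Cy5 (adjusted p = 0.0511). In the skeletal muscle list 6 of 23 fell and 1 rose (median -0.34), and camera did not pass (adjusted p = 0.0539). It passed without arrays 3 (0.0478) or 4 (0.0398) with fetal RNA in Cy5 and without array 1 (0.0455) with adult RNA in Cy5, and its adjusted p was 0.191 with an estimated correlation. Myoglobin, MB, was 8.59-fold lower (-3.10 ± 0.08), the myosin heavy chains MYH2 and MYH1 stood at -2.75 ± 0.19 and -2.23 ± 0.88, and the fast troponin C gene TNNC2 at -2.19 ± 0.16, while TNNI2, the fast troponin I, was the member that rose (1.902). The cells that made these transcripts were not told apart, so these ratios need not reflect skeletal muscle.

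The other 7 lists did not pass camera. Glycolysis and glucose uptake genes went both ways, 4 up and 4 down of 26 (median -0.23, adjusted p = 0.438): the glucose transporters SLC2A1 (2.10 ± 0.06, 4.28-fold) and SLC2A3 (1.52 ± 0.13) rose, and the muscle enzymes PGAM2 (-1.78 ± 0.30) and PFKM (-1.54 ± 0.11) fell. SLC2A3 left the threshold with 1 probe per gene (0.91). Of 36 calcium handling and channel genes 9 fell and 1 rose (median -0.16, adjusted p = 0.142), with sarcolipin, SLN, at -2.45 ± 0.13, the calcium sensor S100A1 at -2.35 ± 0.18, HRC at -1.81 ± 0.40, the ryanodine receptor RYR2 at -1.69 ± 0.13 and the calcium pump ATP2A2 at -1.38 ± 0.18; the potassium channel KCNJ2 rose (1.10). Of 32 cardiac transcription factors and signals 2 rose and 1 fell (median 0.00415, adjusted p = 0.762): GATA6 (1.46 ± 0.11), TCF21 (1.05 ± 0.32) and HEY2 (-1.42 ± 0.16). TCF21 left the threshold on the arrays with adult RNA in Cy5 alone (0.75). NKX2-5 had a ratio of -0.73 ± 0.58, with -0.19 and -1.27 in the 2 orientations, so it passed with adult RNA in Cy5 alone. GATA4 stood at 0.07 ± 0.14 (adjusted p = 0.206 in limma), with its 2 probes at -0.35 and 0.50.

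The lists named for other cell types varied by gene. Which cells made these transcripts was not measured, so a change need not lie in the cells a list is named for. Among 22 endothelial markers SELE alone passed; the list's median was -0.15 and its mean 0.16, opposite in sign (adjusted p = 0.8). Of 17 smooth muscle and pericyte markers 3 fell (median -0.26, adjusted p = 0.723), namely desmin, DES (-2.94 ± 0.17), ACTA2 (-1.16 ± 0.29) and SYNPO2 (-1.16 ± 0.10); ACTA2 left the threshold with fetal RNA in Cy5 alone (-0.90), and the 3 SYNPO2 probes ranged from -2.26 to 0.00120. Of 17 neural and Schwann markers 1 fell, CHGB, a granin of secretory granules (-2.69 ± 0.09; list median -0.16, adjusted p = 0.269). Of 20 hepatic and plasma protein genes 4 rose and 6 fell, with a median of -0.04 and a mean of 0.04, again opposite in sign (adjusted p = 0.857). Albumin, ALB, was 12.7-fold higher (3.67 ± 0.38) and FGG 3.43-fold (1.78 ± 0.25), while RBP4 (-2.13 ± 0.12) and HP (-1.75 ± 0.28) fell.

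**Figure D3:**
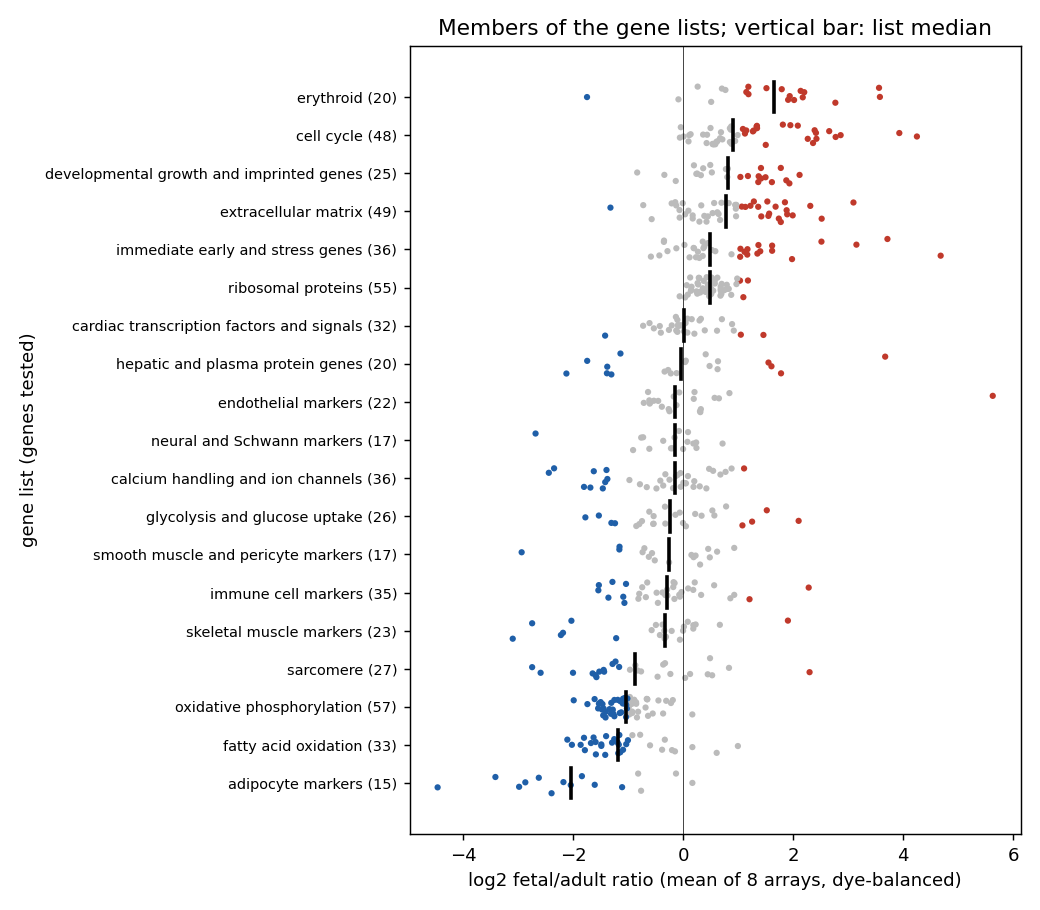
Log2 fetal/adult ratio (horizontal axis, mean over the arrays) of the tested members of the 19 gene lists (vertical axis, with the number tested); red points are higher in fetal and blue points higher in adult RNA past the threshold, grey points did not pass, and black bars mark list medians. Medians run from 1.65 for erythroid genes to -2.05 for adipocyte markers.

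The remaining panel genes were as follows. IGF2, a fetal growth factor, had a ratio of 0.77 ± 0.14 (1.71-fold), with its 2 probes at 0.38 and 1.17. The control genes GAPDH and ACTB stood at -0.86 ± 0.37 and -0.33 ± 0.29, both negative under median centring (-0.84 and -0.32) and scale normalization (-0.83 and -0.30). GAPDH passed the size threshold on the arrays with adult RNA in Cy5 alone (-1.20). For ACTB, 2 of 4 probes were negative (-0.88 and -0.96) and 2 positive (0.23 and 0.30), so no direction is given for it. NPPB, encoding a natriuretic peptide, was measured only on the 4 arrays with adult RNA in Cy5 (2.21 ± 0.06), as was NPPA on 3 of them (0.03 ± 0.03), and the fetal globin HBG1 was measured on 2 of them (3.06 and 2.82 for its 2 probes); these were not tested. MYH7 and HBG2 were not analysed here.

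Dye bias past 0.5 was found for 615 of 29040 probes (2.12%), 274 brighter in Cy5 and 341 brighter in Cy3. The median absolute orientation coefficient was 0.12 and the largest 1.69, and 13014 probes (44.8%) met the adjusted p alone. For 18 of the 1872 called genes the coefficient exceeded 50% of the ratio. Probes of one gene often differed: over the 7390 genes with several probes the median range was 0.39, and for 1069 genes it exceeded 1. In 10 genes, probes were called in opposite directions, among them the M-band gene MYOM1, with probes at 1.67 and -1.03, and PDLIM5, a Z-disc adaptor, with 3 probes between 1.06 and 1.42 and 1 at -1.73.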

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

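The tests of unnamed features in this part were chosen after the results were seen. Of 195 groups of 4 arrays examined, 13 had 1 array whose gap to the nearest other exceeded the 5% critical share of the range in a Dixon test, against 9.75 expected by chance, so most such cases are within chance. On the arrays with fetal RNA in Cy5, HBE1 stood at 5.25 on array 4 against 2.26 to 2.64 on the others; the HBE1 probe near 0 was blank on that array, so its average rested on the other probe there, whose values were 5.18 to 5.38 on all 4 arrays. TOP2A stood at 5.28 on array 2 against 3.92 to 4.09, and IGF2 at 1.01 on array 3 against 0.85 to 0.86. MYOM2 was -2.56 on array 1 where the other 3 shared -2.59, and POSTN was 3.06 on array 3 where the others shared 3.29. On the arrays with adult RNA in Cy5, S100A1 stood at -2.66 on array 3 against -2.46 to -2.43. In 5 further genes 1 array differed from 3 with identical rounded values: ATP2A2 (-1.52 on array 4 against -1.56), CFD (-4.52 on array 3 against -4.42), MB (-2.96 on array 4 against -3.16), MYL2 (-1.96 on array 1 against -1.93) and S100A8 (2.39 on array 1 against 2.36).

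Blank probes were uneven. With fetal RNA in Cy5, array 4 had 198 blank annotated probes against 18 to 25 on the others, and with adult RNA in Cy5, array 3 had 686 against 6 to 68. Without the first of these arrays 1856 genes passed, and without the second 1878, against 1872.

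Features without a gene name also carried signal outside the comparisons of the report. Of 14791 such features tested, 1747 passed the same threshold, 912 higher in fetal and 835 higher in adult RNA. A further group of 728 unnamed features lay below -2 on the deposited ratio in log2 in both dye orientations, where 0 annotated probes did, and this ratio did not turn with the dyes; across unnamed features the arrays of opposite orientation correlated at a mean of 0.598 as deposited.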

How the results depend on the processing

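The alternatives using all features, exact zeros as missing and the removal of 4 of the 12 later lists were chosen after seeing the data. None of the reported list tests and named-gene calls reversed, although 10 of all gene calls changed sign with 1 probe per gene. The balance of the counts did turn with no size threshold, where more genes and probes were higher in adult than in fetal RNA. Of the comparisons of alternatives with the reported counts, agreement and list tests, 495 kept their side of the threshold or lay within 1.5 times the count, 27 moved, 6 gained and 4 lost the call as listed here; of those for named genes 1806 were unchanged, 3 gained and 12 lost the call. At 1.5-fold, 8323 probes (4587 fetal, 3736 adult) and 4643 genes (2437 and 2206) passed; with no size threshold, 21571 probes (10157 and 11414), 13454 genes (6130 and 7324) and 13014 dye-biased probes (6029 brighter in Cy5, 6985 in Cy3) did, by construction of a lower bar. Read as log2, the values gave 74 probes (59 and 15) and 46 genes (37 and 9), because every ratio shrinks. With all features, 5237 probes passed, 2258 of them towards adult, dye bias was called for 1719 (474 and 1245) and mean agreement was 0.921. More features were tested, and 1157 of the dye calls were unnamed features. Among the unnamed features, 728 lay below -2 on the deposited ratio in log2 in both orientations, so their ratio did not turn with the dyes. How far such features raised the agreement was not measured. The immune list's adjusted p was 0.0694 for probes on all 8 arrays, 0.076 with an estimated correlation, 0.0538 with zeros missing, and 0.0302 to 0.0511 leaving out each array. The skeletal muscle list passed on all 8 arrays (0.0452), against random lists (0.0114) and with zeros missing (0.0488), and ranged from 0.0398 to 0.0709 leaving out each array. For both lists the cause was not tested.

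Leaving out each array gave 1856 to 1879 genes, with 97.4% to 98.3% of the reported calls kept. Arrays with fetal RNA in Cy5 alone gave 1949 genes (84% kept), those with adult RNA in Cy5 alone 2165 (90.1%), and 1 probe per gene 2068 (91.9%). Same-numbered arrays of the 2 orientations did not deviate together (r from -0.0889 to 0.055, other numbers -0.0849 to 0.104, and 0 of 4 numbers matched best with their own), so the numbers do not pair the arrays; with the number as a replicate block 1868 genes passed, all among the reported ones. Removal of the kidney, epithelial, neutrophil granule and cytokine genes left 1796 calls. Signal over background was not used here, so its limit on dim probes was not measured.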

Other observations

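In this part the tests of mesothelial cells, dye bias, leukocytes, neutrophil precursors, noise and transcripts were chosen after the results were seen, and all 12 gene lists were written after the largest ratios had been seen. Inflammatory signalling genes were high in the fetal RNA well beyond those already named. In a list of 37 NF-kappa-B and cytokine response genes 31 were higher in fetal RNA and 0 in adult (median 2.95, camera adjusted p = 3.9e-16, adjusted p = 0.000759 with an estimated correlation). Of these 31 genes, 23 had ratios above 1.9, which had been seen before the list was written. Among them were CXCL1, CXCL8, PTX3, SELE and IL6, which prompted the list. Its camera values therefore largely test genes picked for being high. Its 14 members with an absolute ratio of 1.9 or less had a median of 1.18 (permutation against random lists, p = 2e-04). CSF3 (4.49), PTGS2 (4.33), TNFAIP6 (4.27), VCAM1 (3.58) and the feedback inhibitor NFKBIA (2.21) were among the larger ratios of the list, not among these 14, while TNF stood at -0.07. Interferon-stimulated genes did not follow: 6 of 29 were higher in adult RNA, among them IFI27 (-1.94) and IFIT1 (-1.75), and 1 in fetal RNA, ISG20 (median -0.27, camera adjusted p = 0.0917; permutation against random lists, unadjusted p = 0.014).

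Markers of epithelia and of the kidney were also higher in the fetal RNA. In the epithelial list 12 of 24 rose and 0 fell (median 0.99, camera adjusted p = 4.05e-05, adjusted p = 0.023 with an estimated correlation), with CDH1 at 3.79 and CD24 at 2.86 besides EPCAM, which prompted the list. Of these 12 genes, 6 had ratios above 1.9, seen before the list was written, so its camera values partly test genes picked for being high. The 18 epithelial members with an absolute ratio of 1.9 or less had a median of 0.411 (permutation against random lists, p = 0.0042). In the kidney list 22 of 62 rose and 1 fell (median 0.57, camera adjusted p = 4.05e-05, adjusted p = 0.0103 with an estimated correlation), with CDH16 at 4.41, FXYD2 at 2.83 and HSD11B2 at 2.71 besides KCNJ16. Of these 22 genes, 19 had ratios above 1.9, which had been seen before the list was written. The camera values of the kidney list therefore partly test genes picked for being high, and its contrast with the organ lists below is not a test. Lists for other organs had medians near 0: lung -0.10 (of 20 markers 0 higher in fetal and 3 in adult RNA), thymus -0.04 (0 and 0 of 18), intestine and stomach -0.06 (0 and 0 of 19), thyroid -0.14 (0 and 0 of 9) and adrenal -0.08 (1 and 1 of 13).

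For the kidney and epithelial pattern, dye bias would turn the sign between orientations. Members that reached 1 on the arrays of one dye orientation had a median of 2.23 on the other, whichever was used to select them (quartiles 1.59 to 2.74 for 35 genes and 1.51 to 2.58 for 37). However, 19 kidney and 6 epithelial genes had ratios above 1.9, seen as means over both orientations before the lists were written. A positive median on the other orientation was therefore largely fixed in advance, and nothing about dye bias is concluded from it. For mesothelial or epicardial cells most of 17 markers were negative (median -0.245, quartiles -0.523 to -0.0311, CALB2 -2.05 and ITLN1 -2.32), but the epicardial gene TCF21 rose (1.05) and WT1 stood at 0.92, so these cells stay open. Kidney RNA in the fetal preparation remains open: kidney markers with an absolute ratio of 1.9 or less had a median of 0.181 (43 genes, permutation against random lists, p = 0.0152), below the 0.3 set before this median was computed, and leaving out the larger ratios lowers this median. Of the 22 kidney markers higher in fetal RNA 19 had the larger ratios and only 3 were among these 43, so their share is not set against that of other organs, and PAX2 (-0.72), SIX2 (-0.11), AQP2 (0.18) and SLC22A6 (-0.30) did not rise. Tissue admixture may or may not account for some of these genes, fetal stage stays open and untested, and 0 of the kidney genes are in the lists fixed in advance.

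For the inflammatory pattern, a larger total share of leukocyte RNA is argued against by a median of 0.026 over 26 pan-leukocyte genes (upper quartile 0.244). Members ran from CD48 at 1.09 to EVI2B at -0.51. The ratios are centred on each array, so numbers of cells were not measured. The median of 2.95 for the cytokine list adds no separate support, since it includes the ratios that prompted that list. The 14 cytokine list members with an absolute ratio of 1.9 or less had a median of 1.18. A changed state of few cells, or a shift between kinds of leukocytes, is not excluded by this. For the granule genes alone, neutrophil precursors stay open: among 23 genes 10 rose (median 0.83, camera adjusted p = 6.5e-05, adjusted p = 0.0134 with an estimated correlation). Of these 10 genes, 6 had ratios above 1.9, seen before the list was written, so these camera values partly test genes picked for being high. Without the larger ratios that prompted the list the median of 17 genes was 0.526 (permutation against random lists, p = 0.0014). Members went apart both among genes made by precursors (MPO 2.97, CTSG 0.83, PRTN3 0.68, ELANE 0.51, AZU1 -0.21) and among those of mature neutrophils (S100A8 2.28, S100A12 1.91, CSF3R 0.01, FCGR3B -0.00303, CXCR2 -0.31), so neither stage is told from these values. Of the 23 genes, 2 are in the lists fixed in advance. Handling of the tissue before RNA preparation and fetal stage were not tested and stay open.

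Noise between arrays was examined for genes with opposed probes, selected by size alone on the arrays of a given dye orientation. Of 18 such genes with fetal RNA in Cy5, 9 kept both signs with adult RNA in Cy5 (50%, exact 95% interval 26% to 74%). Of 17 selected with adult RNA in Cy5, 15 kept both with fetal RNA in Cy5 (88.2%, 63.6% to 98.5%). Noise in both probes would give 25%, so this is argued against for these genes as sets. The first interval lies only just above that share, and genes that lost a sign are not covered. Noise in only either probe of a gene would keep both signs more often than 25%, so it is not excluded. The 10 genes with probes called in opposite directions were selected otherwise, so nothing about noise is concluded for them. Different transcripts remain open: in 5 of the 10 genes the opposed probes carried different accessions, against 37.6% of other probe pairs of one gene (permutation p = 0.302). Probe sequences were not used here, so a probe on another gene stays possible and untested.

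Regrouping the 8 arrays into 4 and 4 in all 35 ways gave as many probes (3491) in 1 split, the real one, with 1 as the highest other. The same held for genes (1872, highest other 1). For probes and genes this drop was built in, since a wrongly assigned array has its ratios turned the wrong way and cancels reproducible differences. Nothing about chance is therefore concluded from the probe and gene counts. For dye-biased probes (615, highest other 1) the ratios kept their real direction and only the orientation was regrouped. A chance arrangement of these arrays is thus argued against for dye bias alone. Chance between RNA preparations is not covered, as the arrays may share extracts. For gene lists, 8 of 35 splits gave at least the 11 lists of the real one (highest other 11), so chance is not excluded by this count. The lists were tested on ratios turned in the same way as those of probes and genes. The 7 others keep 6 of 8 arrays in place, so part of the real difference stays in them. The 18 splits with 4 arrays moved cancel it by construction and gave 0 lists in camera. Nothing about chance is therefore concluded from the list counts either.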
